A study of Mus musculus with 82 samples.

How the data were processed

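The tissue came from mice perfused with 0.5% paraformaldehyde, whose frozen brains were cut on a cryostat onto membrane slides and captured by laser, per the labels' protocols. Ribosomes were immunoprecipitated from the lysate after the method of Sanz and colleagues, RNA was purified with an RNeasy Micro Plus kit, cDNA was amplified with the NuGEN Ovation RNA-Seq V2 kit, libraries were made with the KAPA Hyper Prep kit, and paired-end reads of 50 bases were sequenced on an Illumina HiSeq, per the same protocols. The input was the cleared lysate. The genome build was GRCm38 (mm10) per the submitters' processing notes; the aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. The deposited table held raw counts per gene, whole numbers without normalization, for 48795 gene identifiers, of which 48349 were matched to a symbol. No column was left without a sample.

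Table columns were matched to libraries by the letters and numbers of their names. The letters that separate the regions were read as the models used for white matter stroke (L) and cortical stroke (M), which the labels do not spell out; S was read as sham, ip as immunoprecipitate and b as input. The design text speaks of 4 to 5 samples per zone, and the labels give 5. The labels place no library with an animal, and whether zones of one animal stand in several groups is not given, so no animal could enter the tests. Sequencing batches were not given. No replicate pair matched within sampling noise: the lowest chi-square per degree of freedom over 152 pairs was 3.159, on genes with at least 20 counts.

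Most counts were ribosomal. The mitochondrial ribosomal genes mt-Rnr2 and mt-Rnr1 held 46.7% and 28.6% of all counts, and Gm42418 and CT010467.1, which overlap ribosomal DNA, 6.21% and 2.29%. Gm23935 and Lars2 (0.529% and 0.344%), treated likewise, and the other annotated ribosomal RNA genes were also set aside. The remaining counts had a median of 2487398 per library, and between 6388 and 30269 genes were detected. Libraries with under 10000 detected genes or under 1000000 such counts are called shallow: white matter zone 1 replicates 1 and 5, zone 3 replicate 1, zone 5 replicate 3 and cortex zone 1 replicate 1. CPM are counts per 1000000. For receptor genes, CPM outside ribosomal RNA take these remaining counts as the total. For single genes they take the remaining counts of genes that passed filterByExpr, scaled by TMM over all libraries of the region. Amplified reads without molecular identifiers are not independent molecules, so counting precision is overstated by the totals.

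Each comparison was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts of its groups only, without covariates: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a robust quasi-likelihood fit and its F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the fold change divided by the square root of F. Differences between regions, and between stroke and uninjured enrichment, were interaction contrasts of 4 group means. The 24 comparisons, the groups and the lists were fixed before the data were examined.

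The 31 gene lists were tested with camera of limma 3.58.1 with the correlation between genes estimated from the residuals, for lists of at least 3 tested genes, adjusted over the lists of a comparison; a preset correlation of 0.01 and fry were alternatives. They cover markers of astrocytes, neurons, oligodendrocytes, their precursors, microglia and macrophages, blood leukocytes, endothelial, mural, fibroblast and ependymal cells and red blood cells. They also cover pan-reactive, A1-type and A2-type astrocyte genes, glutamate, potassium and water handling, interferon response, antigen presentation, complement, chemokines and cytokines, STAT3 and gp130 signalling, proteoglycans, collagens and basement membrane, and matrix proteases and inhibitors. The remaining lists are cholesterol synthesis, lipid transport and storage, cell cycle, hypoxia and glycolysis, metallothioneins and NRF2 targets, phagocytosis and lysosome, synaptogenic and growth factors, and immediate early genes. Some genes stand in more than 1 list. A member entered a comparison if its counts passed the filter there, which it could do through the group where it was high. The share of members that rose, and the list tests, therefore partly rest on that filter.

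A gene could be named if it was among the 6 largest rises or 6 largest falls past the threshold with a mean of at least 1 log2 CPM and, between 2 groups, no overlap of libraries, leaving out predicted genes, ribosomal proteins, mitochondrial genes and small RNAs. It could also be named as 1 of up to 4 list members with the lowest adjusted p, as the list member with the highest mean among those that did not pass, or as 1 of 13 reference genes. From these, genes with under 10 counts summed over either group were left out of the text, as were most whose call did not hold with a library left out; that choice was made after the values were seen. In uninjured cortex IP Cd44, Serping1, C1qa and C4b had 10, 12, 20 and 22 counts over the 5 libraries, so their fold changes rest on few counts. How reads of near-identical, overlapping or antisense genes were shared is not given, so values of C4b, H2-D1, H2-K1, Serpina3n, Ifit1 and Lyz2 are uncertain. Results for some genes that the rule allows are not reported here. Coordinates come from GENCODE vM21, which is on GRCm38.

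Alternatives were DESeq2's median-of-ratios size factors in edgeR (RLE), no low-count filter, a filter at CPM over 1, DESeq2 1.42.0 with its Wald test, limma voom with sample quality weights, the replicate number as a block, all IP groups in one fit, and each library left out in turn; fits without the shallow libraries were added after the data were seen. Other splits of the libraries were limited to 22 per comparison by run time. The tests were tried on simulated counts with 200 genes changed, drawn from the means and library sizes of the real libraries. The changed genes were taken only from those with higher mean counts, so the recovered shares below do not cover genes with low counts. In cortex zone 1 (12178 genes) 38.8% of 2-fold, 97% of 4-fold and 100% of 8-fold changes were recovered, with 6 false calls among 163. In white matter zone 1 (10169 genes) 0%, 7.5% and 27.3% were recovered, with 1 false call among 24. In uninjured cortex IP against input (11201 genes) these shares were 35.8%, 100% and 100% (4 false calls among 161), in white matter stroke IP against input (11388 genes) 0%, 1.5% and 27% (4 among 22), and in the zone 1 region difference (14335 genes) 0%, 0% and 16.7% (0 among 11). Figures were drawn from the same values.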

Results

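RNA immunoprecipitated with ribosomes, and input RNA, were measured in laser-captured mouse brain tissue. The tissue was taken after stroke in the white matter or in the cortex, and from the same regions of uninjured (sham) mice. The series describes the immunoprecipitated (IP) samples as enriched for astrocytes, the glial cells that take up glutamate and respond to injury. Its input samples are the cleared lysate from which the ribosomes were pulled. The 82 libraries formed 18 groups. Each region had 5 IP libraries in each of 5 numbered stroke zones, 5 IP and 5 input libraries of uninjured tissue, and 3 IP and 3 input libraries of stroke zones 1 to 3 taken as one area. The labels number the zones without giving their distance from the lesion, and they do not tie libraries to animals. Which libraries share an animal is not given, so the p-values measure the spread between these libraries.

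Total counts per library ran from 2518604 to 28245109, with a median of 16979389.5. Mitochondrial ribosomal RNA took between 39.92% and 90.66% of these counts, and counts outside ribosomal RNA and genes overlapping ribosomal DNA ran from 389882 to 5708605. The mean mitochondrial ribosomal share was 86.0% in input and 85.0% in IP of uninjured cortex, and 53.7% and 76.6% in uninjured white matter. How much IP RNA was bound to the captured ribosomes was not measured. The median Pearson correlation of log2 counts between replicates, taken across genes, was 0.408 over the white matter groups and 0.886 over the cortex groups. Group medians were 0.495 and 0.548 in cortex input of uninjured and stroke tissue, and 0.5735 and 0.426 in white matter input. Fold changes are given on the log2 scale with their standard error (±), from edgeR's quasi-likelihood test, with 5 libraries in each group except where stated.

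Positions of the genes most often named follow GRCm38. Gfap (ENSMUSG00000020932), the intermediate filament of astrocytes, lies on chromosome 11 from 102887336 to 102900912. The filament gene Vim (ENSMUSG00000026728) lies on chromosome 2 from 13573927 to 13582826, and the water channel gene Aqp4 (ENSMUSG00000024411) on chromosome 18 from 15389496 to 15410982. The complement genes C4b (ENSMUSG00000073418) and C1qb (ENSMUSG00000036905) lie on chromosome 17 from 34728380 to 34743882 and on chromosome 4 from 136880129 to 136886187. Ctsd (ENSMUSG00000007891), a lysosomal protease, lies on chromosome 7 from 142375911 to 142388038. Hmgcs1 (ENSMUSG00000093930), an enzyme of cholesterol synthesis, lies on chromosome 13 from 119690379 to 119708260, and the long non-coding RNA Malat1 (ENSMUSG00000092341) on chromosome 19 from 5795690 to 5802672. All of these except Malat1 are annotated as protein-coding.

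Enrichment was assessed by comparing IP with input of the same cohort. In uninjured cortex, several astrocyte and neuronal genes were higher in IP than in input, and 2 microglial markers were lower. No marker list stood apart from other genes as a group, as given below. Among astrocyte genes, Ndrg2 was higher by 1.13 ± 0.25. Among neuronal genes, the kinase gene Camk2a was higher by 1.26 ± 0.28 and the vesicular glutamate transporter gene Slc17a7 by 1.74 ± 0.28, while the calcium sensor gene Vsnl1 was lower, at −1.79 ± 0.31. The microglial receptor gene P2ry12 was lower in IP, at −2.45 ± 0.52, and the lipoprotein genes Apoe and Lrp1 were higher, at 1.84 ± 0.32 and 1.93 ± 0.24. Among the largest differences were those of Neurl1a (3.79 ± 0.44), Panx2 (3.43 ± 0.56) and Dagla, a lipase of endocannabinoid synthesis (3.18 ± 0.32). Gfap and the glutamate transporter gene Slc1a2 did not pass the test, at −0.92 ± 0.36 and 0.45 ± 0.30.

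Of 20 astrocyte markers tested in uninjured cortex, 3 were higher in IP over all genes and 3 adjusted over the list alone. Of 18 neuron markers, 6 were higher and 2 lower (6 and 3 adjusted over the list alone), and of 11 microglia and macrophage markers 0 were higher and 2 lower (0 and 2 adjusted over the list alone). Of 8 immediate early genes, which respond to neuronal activity, 4 were higher (4 adjusted over the list alone), Arc by 2.56 ± 0.40 and Nr4a1 by 2.18 ± 0.53 (3.25 without input replicate 5). No list passed camera with an estimated correlation, limma's test of a list against other genes; the lowest adjusted p was 0.97. Of 11201 genes tested by edgeR, 1305 were higher and 1597 lower in IP. With the replicate number as a block this balance turned, with more genes higher than lower. Olfactory and vomeronasal receptor genes, which the brain scarcely transcribes, took 2846 ± 2592 CPM outside ribosomal RNA in input and 89.3 ± 28.8 in IP (SD, n = 5 each; 2-sided exact permutation p = 0.00794, the smallest these groups allow), and 1695 ± 355 in input without replicate 1. With no low-count filter edgeR called 1605 higher and 5744 lower.

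**Figure D1:**
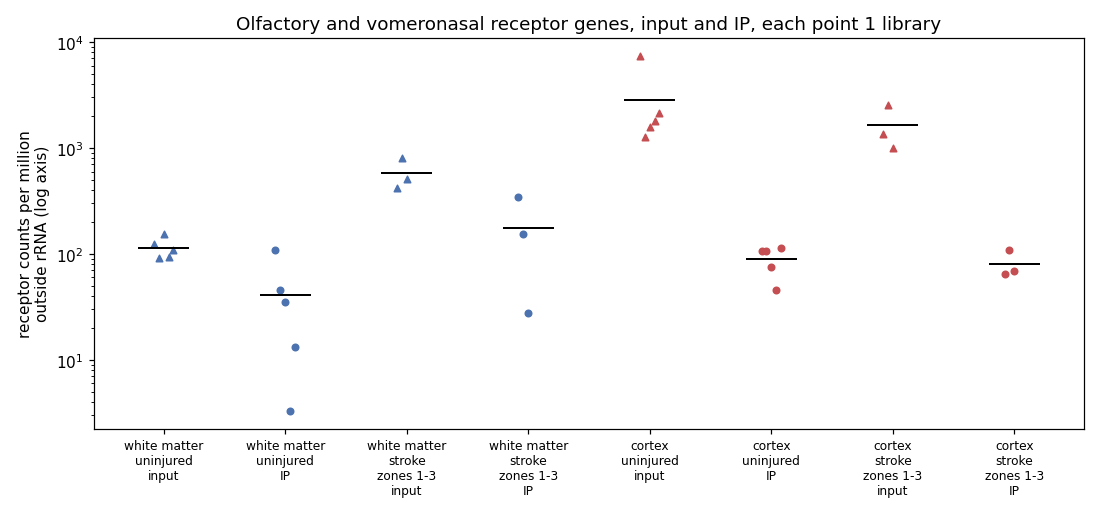
CPM outside ribosomal RNA (log axis) of 1837 olfactory and vomeronasal receptor genes in input (triangles) and IP (circles) of each region and cohort, with each point 1 library and each bar the group mean. The cortex input libraries sit at 994.5 or above and the cortex IP libraries at 114.4 or below.

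In cortex stroke zones 1 to 3 (n = 3 IP and 3 input), the astrocyte genes Ndrg2, Sox9 and S100b were higher in IP by 1.38 ± 0.18, 1.69 ± 0.37 and 1.13 ± 0.26, and the GABA transporter gene Slc6a11 by 2.79 ± 0.31. Neuronal Camk2a was higher by 1.57 ± 0.12 and Slc17a7 by 1.68 ± 0.17. P2ry12 was lower at −2.93 ± 0.45, as were the antigen presentation gene B2m (−1.93 ± 0.22) and the interferon-induced gene Oasl2 (−2.20 ± 0.41, or −1.57 without input replicate 2). Myelin Mbp was higher by 1.91 ± 0.16. Gfap did not pass, at 0.59 ± 0.24 (edgeR adjusted p = 0.0798). Of 20 astrocyte markers, 4 were higher (4 adjusted over the list alone), and of 18 neuron markers 8 were higher and 3 lower (8 and 4 adjusted over the list alone). Of 16 microglia and macrophage markers, 1 was higher and 2 were lower (2 and 4 adjusted over the list alone). The test called 1630 genes higher and 1849 lower of 11280, and no list passed camera, with a lowest adjusted p of 0.89. Receptor genes took 1638 ± 819 CPM outside ribosomal RNA in input and 81.1 ± 23.9 in IP (SD, n = 3 each; 2-sided exact permutation p = 0.1, the smallest these groups allow). Without IP replicate 1, 2 or 3 the count of called genes was 1538, 1663 or 1492 and more were higher than lower (856 and 682, 891 and 772, 870 and 622). Without input replicate 2 the count was 5329.

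In uninjured white matter, the neuronal kinase gene Camk2a was higher in IP than in input, by 2.58 ± 0.33, as were Slc1a2 (1.14 ± 0.18) and the myelin gene Mbp (1.36 ± 0.21), whose call was lost with limma voom and with no low-count filter. The DNA repair gene Rad52 was lower in IP, at −3.07 ± 0.33. Gfap did not pass, at 0.08 ± 0.18 (−0.04 without input replicate 4). Of 20 astrocyte markers 1 was higher (5 adjusted over the list alone), of 16 oligodendrocyte markers 3 (4, list alone), and of 15 neuron markers 1 (4, list alone). edgeR called 63 genes higher and 10 lower of 12151, and no list passed camera, with a lowest adjusted p of 0.23. Receptor genes took 115 ± 25.9 CPM outside ribosomal RNA in input and 41.2 ± 41.2 in IP (SD, n = 5 each; 2-sided exact permutation p = 0.0238), or 24.4 ± 19.6 in IP without IP replicate 1 (exact p = 0.00794). Leaving out input replicate 5 gave 32 called genes and leaving out IP replicate 1 gave 121. In white matter stroke zones 1 to 3 (n = 3 and 3), edgeR called 0 of 11388 genes, with 764 at an unadjusted p under 0.05, 137 called by DESeq2 and 0 by limma voom. Slc1a2 stood at 1.21 ± 0.37 there and Gfap at −0.07 ± 0.37, or 0.30 without input replicate 1 and 0.11 with limma voom. Of 20 astrocyte markers 0 passed (0 adjusted over the list alone), and camera called no list, with a lowest adjusted p of 0.4.

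Whether enrichment differed between stroke and uninjured tissue was tested as an interaction. edgeR called 0 of 16164 genes in white matter, where 1512 had an unadjusted p under 0.05, DESeq2 called 134 and limma voom 0. Gfap enrichment differed there by −0.16 ± 0.35 and Slc1a2 enrichment by 0.06 ± 0.34, with signs that turned without single libraries (Gfap 0.23 without stroke input replicate 1, Slc1a2 −0.13 without stroke input replicate 3). In cortex edgeR called 0 of 16391 genes, 782 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0. The difference was 1.40 ± 0.51 for Gfap, −0.36 ± 0.62 for Aqp4 and −0.15 ± 0.45 for Slc1a2, and none of them passed. The sign of Aqp4 turned with limma voom (0.49) and without stroke input replicate 2 (0.65), and that of Slc1a2 with limma voom and without uninjured input replicate 1 or uninjured IP replicate 4.

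Uninjured cortex and white matter IP differed most plainly in myelin and neuronal genes. The myelin genes Mag and Mbp were lower in cortex, at −5.38 ± 0.31 and −4.94 ± 0.32, and the oligodendrocyte transcription factor gene Sox10, at −4.50 ± 0.28. Neuronal genes were higher in cortex, with Snap25 at 3.59 ± 0.24 and the neurofilament genes Nefl and Nefm at 3.96 ± 0.40 and 5.38 ± 0.58 (Nefm 6.17 without white matter IP replicate 4). Gfap was lower in cortex, at −4.14 ± 0.26, as were Aqp4 (−2.37 ± 0.35), Vim (−2.36 ± 0.51) and C4b (−4.99 ± 0.69), whereas Slc1a2 did not pass (−0.49 ± 0.24). The chondroitin sulphate proteoglycan gene Vcan was lower (−3.75 ± 0.36) and the perineuronal link protein gene Hapln4 higher (5.33 ± 0.66, or 6.46 without white matter IP replicate 1).

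All 15 of 15 oligodendrocyte markers tested were lower in cortex (15 adjusted over the list alone, camera adjusted p = 0.000128). Of 18 neuron markers 14 were higher (16 adjusted over the list alone, camera adjusted p = 0.02), and of 10 oligodendrocyte precursor markers 6 were lower (6 adjusted over the list alone, camera adjusted p = 0.02). Of 20 astrocyte markers 7 were lower (10 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.264). Of 11245 genes, edgeR called 1374 higher and 1730 lower in cortex, whereas limma voom called 2089 higher and 1661 lower. Size factors from DESeq2's method in place of TMM moved the median fold change of all genes by 0.103.

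Each stroke zone was compared with uninjured IP of its region to measure the response to stroke. In cortex zone 1, reactive astrocyte genes, microglial genes and myelin genes rose. Mitochondrial ribosomal RNA took 65.4% of all counts there (59.43% to 74.52%) and 85.0% in uninjured IP (78.36% to 89.94%), and mitochondrial mRNA 7.79% and 15.9% of the rest. Gfap rose by 3.42 ± 0.27, from 99.1 ± 30.9 to 1055 ± 294 CPM outside ribosomal RNA (SD, n = 5), Vim by 5.65 ± 0.42, the protease inhibitor gene Serpina3n by 5.10 ± 0.61 (5.72 without uninjured IP replicate 2), and Aqp4 by 2.05 ± 0.23. C1qb rose by 4.44 ± 0.29, the microglial receptor genes Csf1r and Cx3cr1 by 3.01 ± 0.25 and 2.46 ± 0.29, and the lysosomal protease gene Ctsd by 3.91 ± 0.24. Among the falls, the activity-regulated transcription factor gene Npas4 dropped by 3.35 ± 0.66 (−4.45 without zone 1 replicate 5) and Hmgcs1 by 1.73 ± 0.33. Slc1a2 and Snap25 did not pass, at 0.11 ± 0.21 (−0.02 without zone 1 replicate 5) and −0.38 ± 0.20. Of 12178 genes tested, edgeR called 607 higher and 78 lower, and 656 in all without the shallow replicate 1 of zone 1. With all IP groups in one fit it called many more genes.

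Of 7 pan-reactive astrocyte genes tested in cortex zone 1, 5 rose (7 adjusted over the list alone), with a median of 3.42 and a camera adjusted p of 0.00238; the hyaluronan receptor gene Cd44 rose by 5.31 ± 0.86 (4.62 without zone 1 replicate 1 and 6.06 without uninjured IP replicate 3). The A1-type list had 3 of 5 rises (3 adjusted over the list alone, camera adjusted p = 0.00362), with the class I antigen gene H2-D1 at 3.01 ± 0.39 and the complement inhibitor gene Serping1 at 4.24 ± 0.86. The A2-type list had 2 of 5 (2 adjusted over the list alone, camera adjusted p = 0.0177). Counts allowed tests of 0 of 12 A1-type and 1 of 12 A2-type members in uninjured cortex IP against input. Those tested here can therefore have passed the filter through zone 1, and their rises and list tests partly rest on it. Among 20 astrocyte markers 3 rose and 1 fell (6 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.123). Aldh1l1, a folate enzyme gene used as an astrocyte marker, did not pass, at 1.14 ± 0.38. Of 17 genes of glutamate, potassium and water handling 2 rose (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.173), the potassium channel gene Kcnj10 by 1.34 ± 0.25.

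Markers of other cell types moved with these genes in cortex zone 1. All 16 of 16 microglia and macrophage markers rose (16 adjusted over the list alone, median 3.50, camera adjusted p = 0.00104), with C1qc at 4.13 ± 0.36. Of 14 oligodendrocyte markers 10 rose (13 adjusted over the list alone, camera adjusted p = 0.00369), with Mbp at 1.40 ± 0.19 and Cldn11 at 3.50 ± 0.32. Of 11 precursor markers 6 rose (8 adjusted over the list alone, camera adjusted p = 0.00418), the receptor gene Gpr17 by 2.78 ± 0.37. Neuron markers counted 2 falls of 18 (2 adjusted over the list alone, camera adjusted p = 0.311). Endothelial markers counted 2 rises of 12 (2 adjusted over the list alone, camera adjusted p = 0.0975), the von Willebrand factor gene Vwf by 2.83 ± 0.48. Mural cell markers counted 0 of 5 (1 adjusted over the list alone, camera adjusted p = 0.224) and fibroblast markers 1 of 3 (1 adjusted over the list alone, camera adjusted p = 0.207). Of 2 red blood cell genes tested 0 passed (1 fell adjusted over the list alone), too few for camera. No blood leukocyte or ependymal marker had enough counts to be tested.

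Immune and matrix genes rose as groups in cortex zone 1. Of 9 complement genes 8 rose (8 adjusted over the list alone, median 4.24, camera adjusted p = 0.00238), with C4b at 5.64 ± 0.58 and C1qa at 4.61 ± 0.56. That list is not separate from the others, since 5 of its 16 members stand in another list, C1qc among the microglia markers. Of 8 interferon response genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00319), including Oasl2 (4.82 ± 0.47) and Ifit1 (3.74 ± 0.56). Of 9 antigen presentation genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00238), B2m by 2.62 ± 0.23 and H2-K1 by 3.12 ± 0.35. Yet Oasl2 and B2m were lower in IP than in input of cortex stroke zones 1 to 3, at −2.20 and −1.93 (n = 3 each). C4b averaged 25.64 CPM outside ribosomal RNA in IP and 17.78 in input there. Which cells gave the rises in zone 1 was not measured. Chemokine and cytokine genes counted 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.00432), with the alarmin gene Il33 at 2.07 ± 0.30 and the growth factor gene Csf1 at 2.42 ± 0.43. Counts of uninjured cortex IP and input allowed tests of 2 of 16 interferon, 3 of 15 antigen presentation and 3 of 20 chemokine and cytokine members. Those tested in zone 1 can therefore have passed the filter through their counts there. STAT3 and gp130 signalling counted 4 of 9 (5 adjusted over the list alone, camera adjusted p = 0.00606), the oncostatin M receptor gene Osmr by 3.13 ± 0.55. Proteoglycan and perineuronal matrix genes counted 5 of 11 (7 adjusted over the list alone, camera adjusted p = 0.0042), collagen and basement membrane genes 5 of 15 (7 adjusted over the list alone, camera adjusted p = 0.00418), and matrix proteases and inhibitors 5 of 7 (5 adjusted over the list alone, camera adjusted p = 0.00238). Vcan rose by 1.89 ± 0.30, the fibronectin gene Fn1 by 3.07 ± 0.48 (3.72 without uninjured IP replicate 4), the matrix glycoprotein gene Sparc by 2.44 ± 0.21 and the cathepsin gene Ctss by 2.83 ± 0.45.

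Lipid genes split in cortex zone 1. Of 17 cholesterol synthesis genes 2 fell (3 adjusted over the list alone, median −0.63, camera adjusted p = 0.0071), whereas of 14 lipid transport and storage genes 8 rose (10 adjusted over the list alone, median 1.60, camera adjusted p = 0.00238). The cholesterol exporter gene Abca1 rose by 3.20 ± 0.25, the lipocalin gene Apod by 3.49 ± 0.31 and Apoe by 1.59 ± 0.25. Of 15 phagocytosis and lysosome genes 11 rose (12 adjusted over the list alone, camera adjusted p = 0.00238), with the integrin gene Itgb5 at 3.08 ± 0.34 and Ctsz at 3.41 ± 0.38. Of 7 cell cycle genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.00418), the kinesin gene Cenpe by 3.25 ± 0.73, a call lost with limma voom. Counts of uninjured cortex IP and input allowed tests of 2 of 19 cell cycle members, so members can have passed the filter through zone 1. Synaptogenic and growth factor genes counted 3 rises of 12 (3 adjusted over the list alone, camera adjusted p = 0.0216), the BMP antagonist gene Chrdl1 by 2.03 ± 0.41. These lists did not pass camera: hypoxia and glycolysis with 2 rises of 16 (2 adjusted over the list alone, adjusted p = 0.216), metallothioneins and NRF2 targets with 2 of 13 (4 adjusted over the list alone, adjusted p = 0.0714), and immediate early genes with 1 fall of 8 (3 adjusted over the list alone, adjusted p = 0.182).

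**Figure D2:**
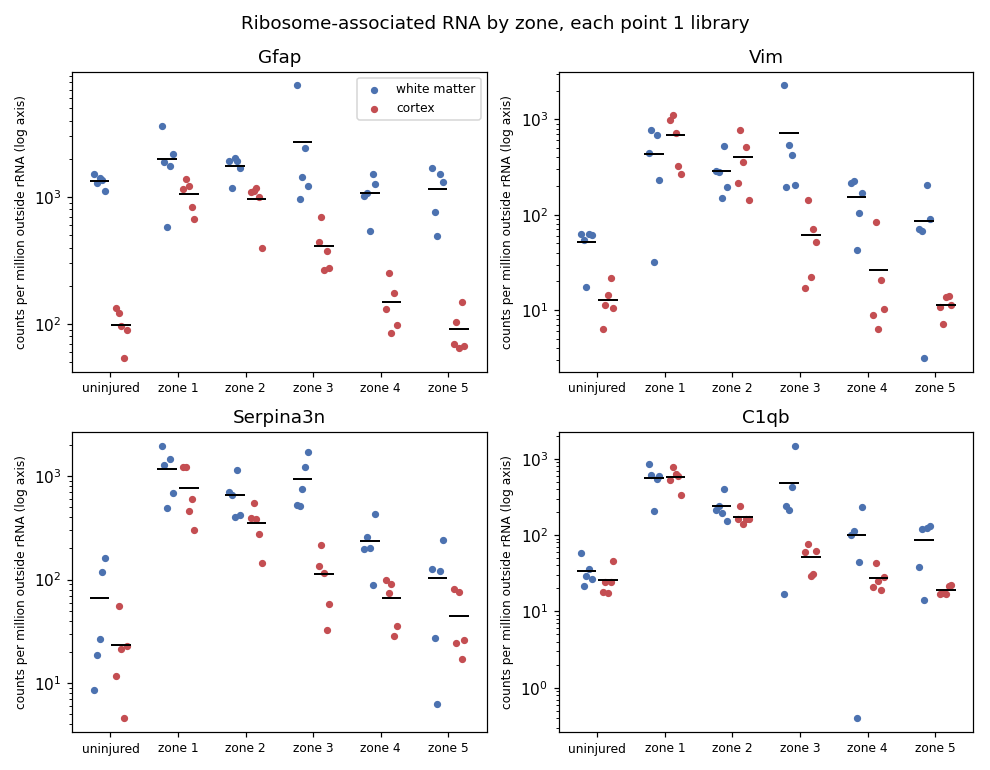
CPM outside ribosomal RNA (log axis) of Gfap, Vim, Serpina3n and C1qb in IP libraries of uninjured tissue and stroke zones 1 to 5 of white matter (blue) and cortex (red), with each point 1 library and each bar the mean of 5. In cortex Gfap averaged 1055 in zone 1, 960.1 in zone 2, 410.4 in zone 3, 149 in zone 4, 90.7 in zone 5 and 99.1 in uninjured tissue.

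In cortex zone 2, Gfap rose by 3.29 ± 0.33, Vim by 4.83 ± 0.57, C4b by 5.18 ± 0.47, Aqp4 by 2.06 ± 0.20 and the lysozyme gene Lyz2 by 3.55 ± 0.39. Abca1 rose by 2.58 ± 0.19 and Ctsd by 2.36 ± 0.18, while Npas4 fell by 2.10 ± 0.37 and Hmgcs1 by 1.21 ± 0.21. Of 7 pan-reactive astrocyte genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.00118), of 9 interferon genes 8 (9 adjusted over the list alone, camera adjusted p = 0.00449), with the guanylate-binding gene Gbp3 at 3.56 ± 0.46, and of 6 complement genes 6 (6 adjusted over the list alone, camera adjusted p = 0.00118). Microglia and macrophage markers counted 14 rises of 16 (15 adjusted over the list alone, median 2.14, camera adjusted p = 0.0015), with C1qb at 2.68 ± 0.23, and oligodendrocyte markers 7 of 13 (10 adjusted over the list alone, camera adjusted p = 0.0058).

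Cholesterol synthesis genes counted 4 falls of 17 in cortex zone 2 (9 adjusted over the list alone, median −0.78, camera adjusted p = 0.00449). Lipid transport genes counted 8 rises of 13 (11 adjusted over the list alone, camera adjusted p = 0.0015) and phagocytosis genes 9 rises and 1 fall of 15 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00118). The transcription factor gene Stat3 rose by 1.64 ± 0.23, in a list of 9 with 3 rises (4 adjusted over the list alone, camera adjusted p = 0.0151). Astrocyte markers counted 6 rises of 20 (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0645). Slc1a2 did not pass, at 0.47 ± 0.19, nor did Snap25, at −0.13 ± 0.19. edgeR called 377 genes higher and 66 lower of 11857.

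In cortex zone 3, edgeR called 3 of 12022 genes, all higher: Aqp4 by 1.38 ± 0.20, the growth factor binding protein gene Igfbp5 by 1.26 ± 0.17, and the urea transporter gene Slc14a1, named after its values were seen, by 2.01 ± 0.38. Gfap stood at 2.05 ± 0.31 and did not pass (edgeR adjusted p = 0.0577). Gene lists passed camera without any member called over all genes: pan-reactive astrocyte genes (0 of 6, 3 adjusted over the list alone, median 1.45, adjusted p = 0.0284), interferon response (0 of 7, 4 adjusted over the list alone, adjusted p = 0.0284), microglia and macrophage markers (0 of 14, 6 adjusted over the list alone, adjusted p = 0.0318), phagocytosis (0 of 13, 2 adjusted over the list alone, adjusted p = 0.0318) and oligodendrocyte markers (0 of 13, 5 adjusted over the list alone, adjusted p = 0.0422), which did not pass limma's fry (adjusted p = 0.0571). Without uninjured IP replicate 4 the count of genes was 17.

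In cortex zone 4, Gfap stood at 0.57 ± 0.34, Aqp4 at 0.59 ± 0.23 and Serpina3n at 1.55 ± 0.65 (2.15 without uninjured IP replicate 2), and no list passed camera. edgeR called 0 of 12493 genes, 856 had an unadjusted p under 0.05, DESeq2 called 16 and limma voom 0; without uninjured IP replicate 4 edgeR called 12. In cortex zone 5, Gfap stood at −0.14 ± 0.26, Vim at −0.28 ± 0.32 (0.01 without uninjured IP replicate 4) and Aqp4 at 0.35 ± 0.17, and again no list passed camera. edgeR called 0 of 12601 genes, 715 had an unadjusted p under 0.05, and DESeq2 and limma voom each called 0.

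**Figure D3:**
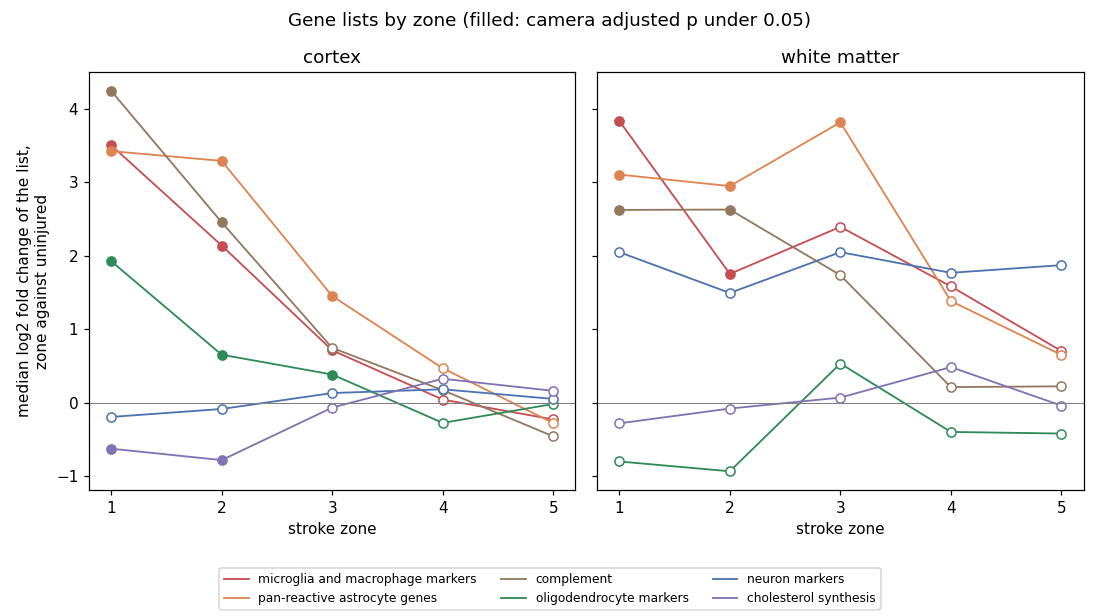
Median log2 fold change of 6 gene lists in each stroke zone against uninjured IP, in cortex (left) and white matter (right), with filled points for lists whose camera adjusted p was under 0.05. Microglia and macrophage markers had medians of 3.50 in cortex zone 1 and 3.83 in white matter zone 1.

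In white matter zone 1, Ctsd rose by 5.07 ± 0.72 (4.05 without zone 1 replicate 1) and Serpina3n by 4.21 ± 0.75 (4.81 without uninjured IP replicate 5), and the microglial genes C1qb and Csf1r rose by 4.12 ± 0.60 and 3.19 ± 0.66. The synaptic vesicle gene Syp rose by 3.93 ± 0.74 (2.81 without zone 1 replicate 1), while Aspa, an oligodendrocyte enzyme gene, fell by 3.06 ± 0.65 (−3.70 without zone 1 replicate 5). Gfap, Vim and Mbp did not pass, at 0.66 ± 0.45, 3.12 ± 0.71 and −1.56 ± 0.46. Mitochondrial mRNA took 8.29% of counts outside ribosomal RNA there (6.41% to 10.29%) and 14.8% in uninjured IP (12.2% to 20.29%), and mitochondrial ribosomal RNA 69.6% and 76.6% of all counts. Of 16 microglia and macrophage markers 6 rose (13 adjusted over the list alone, median 3.83, camera adjusted p = 0.0209), of 7 pan-reactive astrocyte genes 2 (4 adjusted over the list alone, camera adjusted p = 0.0209), and of 8 complement genes 2 (3 adjusted over the list alone, camera adjusted p = 0.0209). Phagocytosis and lysosome genes had 3 of 15 (8 adjusted over the list alone, median 2.02) and did not pass camera (adjusted p = 0.104). Antigen presentation had 1 of 7 (4 adjusted over the list alone, camera adjusted p = 0.0462), lipid transport 0 of 13 (4 adjusted over the list alone, camera adjusted p = 0.0462) and hypoxia and glycolysis 0 of 13 (4 adjusted over the list alone, camera adjusted p = 0.0462). With DESeq2's size factors the antigen presentation list no longer passed (adjusted p = 0.0532).

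Neuron markers in white matter zone 1 counted 1 rise of 17 (12 adjusted over the list alone, median 2.05, camera adjusted p = 0.212), and oligodendrocyte markers 1 fall of 16 (3 adjusted over the list alone, median −0.80, camera adjusted p = 0.389). edgeR called 41 genes higher and 6 lower of 10169. The count was 5 without uninjured IP replicate 2, 270 without zone 1 replicate 1, 410 without both shallow zone 1 libraries, and 14 with all IP groups in one fit. The calls of Csf1r and Aspa were lost without zone 1 replicate 2 or 4 or any of the uninjured IP libraries, that of Syp without uninjured IP replicate 1, 2, 4 or 5, and that of Serpina3n without uninjured IP replicate 2, while Ctsd and C1qb kept theirs with each single library left out. With all IP groups in one fit the calls of C1qb, Csf1r and Aspa were lost, and with DESeq2's size factors that of Aspa. These factors moved the median of all genes by 0.15 and the higher share of calls from 87.2% to 96.9%.

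In white matter zone 2, Ctsd rose by 2.95 ± 0.31, C4b by 2.71 ± 0.37, C1qb by 2.87 ± 0.44, Vim by 2.53 ± 0.45 and Serpina3n by 3.36 ± 0.63 (3.99 without uninjured IP replicate 5). Neuronal Snap25 rose by 2.06 ± 0.36 and Syp by 2.56 ± 0.46, while the glial connexin gene Gjc3 fell by 1.80 ± 0.28. Of 15 microglia and macrophage markers 4 rose (7 adjusted over the list alone, camera adjusted p = 0.00625), of 15 phagocytosis genes 2 (4 adjusted over the list alone, camera adjusted p = 0.00625), of 7 complement genes 3 (3 adjusted over the list alone, camera adjusted p = 0.0107) and of 6 pan-reactive astrocyte genes 2 (4 adjusted over the list alone, camera adjusted p = 0.0134). Of 17 neuron markers 4 rose (9 adjusted over the list alone, camera adjusted p = 0.0866) and of 16 oligodendrocyte markers 2 fell (8 adjusted over the list alone, camera adjusted p = 0.0701). edgeR called 72 genes higher and 29 lower of 10664. With all IP groups in one fit it called 0, without uninjured IP replicate 2 it called 47 and without zone 2 replicate 5 it called 139. DESeq2, limma voom and edgeR with no low-count filter each called more genes, as given below.

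In white matter zone 3, Vim stood at 3.79 ± 0.89, Serpina3n at 3.83 ± 0.93 and Snap25 at 3.05 ± 0.94, none past the test. Without zone 3 replicate 1 Vim stood at 2.73 and Snap25 at 1.497, and without uninjured IP replicate 5 Serpina3n stood at 4.46. The pan-reactive astrocyte list passed camera (0 of 6 members called over all genes, 5 adjusted over the list alone, median 3.81, adjusted p = 0.0179). Microglia and macrophage markers (0 of 15 called, 5 adjusted over the list alone, median 2.39, adjusted p = 0.0709) and neuron markers (0 of 15, 5 adjusted over the list alone, median 2.05, adjusted p = 0.118) did not pass camera. edgeR called 0 of 9292 genes, 1007 had an unadjusted p under 0.05, DESeq2 called 106 and limma voom 13. Malat1 fell by 2.15 ± 0.26 in white matter zone 4 (edgeR adjusted p = 0.0004) and Snap25 rose by 2.60 ± 0.44 (1.90 without zone 4 replicate 3), the vacuolar proton pump gene Atp6v1g2 by 3.06 ± 0.55 and the RNA-binding protein gene Celf4 by 2.27 ± 0.40. Of 17 neuron markers 1 rose (8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.437). edgeR called 7 genes higher and 2 lower of 10612, and limma voom 23 higher and 38 lower. The count was 2 without zone 4 replicate 4 or uninjured IP replicate 1, 2 or 4, 3 without zone 4 replicate 2 or uninjured IP replicate 5, each with 2 lower, and 0 with all IP groups in one fit. The call of Snap25 was lost without zone 4 replicate 4 or any of the uninjured IP libraries, and those of Atp6v1g2 and Celf4 without these or zone 4 replicate 2; Malat1 kept its call with each single library left out. Limma voom ended the call of Atp6v1g2. Snap25 stood at 2.89 ± 0.81 in white matter zone 5 (1.64 without zone 5 replicate 3) and Gfap at −0.22 ± 0.70 (0.03 in DESeq2). Of 17 neuron markers 0 passed (4 adjusted over the list alone, camera adjusted p = 0.148). edgeR called 0 of 10268 genes, 845 had an unadjusted p under 0.05, DESeq2 called 23 and limma voom 0; without zone 5 replicate 1 edgeR called 37.

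Whether the response differed between regions was tested zone by zone, as the change in cortex minus the change in white matter. The regions were read as separate stroke models, and the labels do not match zone numbers between them. Region, model and zone placement therefore cannot be told apart. In zone 1 the change of Gfap was greater in cortex by 2.81 ± 0.52, that of Mbp by 3.00 ± 0.50, of the myelin gene Cldn11 by 4.06 ± 0.60 and of Apod by 3.14 ± 0.52, while that of Syp was lower, at −3.82 ± 0.77 (−2.73 without white matter zone 1 replicate 1). The changes of Vim, Serpina3n and Cx3cr1 did not differ past the threshold, at 2.61 ± 0.80, 0.89 ± 0.91 and −1.27 ± 0.83. Without single libraries Serpina3n ran from 0.25 (white matter uninjured IP replicate 5) to 1.49 (cortex uninjured IP replicate 2) and Cx3cr1 from −1.58 to −0.05 (white matter zone 1 replicates 3 and 1). The sign of Serpina3n turned with limma voom and that of Cx3cr1 without the shallow libraries. Of 16 oligodendrocyte markers 8 were greater in cortex (14 adjusted over the list alone, camera adjusted p = 0.0534), and of 18 neuron markers 2 were lower (12 adjusted over the list alone, camera adjusted p = 0.23). edgeR called 125 genes greater and 149 lower of 14335. More were greater than lower with limma voom (332 and 292), and without any of the 5 cortex zone 1 replicates or without cortex uninjured IP replicate 1, 3 or 4. DESeq2's size factors moved the median of all genes by −0.242 and the split to 75 and 188; leaving out cortex uninjured IP replicate 5 gave 94 genes and white matter zone 1 replicate 1 gave 868.

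In zone 2 the change of Gfap was greater in cortex by 2.85 ± 0.36, of Mag by 2.95 ± 0.48 and of Sox10 by 2.25 ± 0.41, while that of Snap25 was lower, at −2.17 ± 0.44. Of 16 oligodendrocyte markers 11 were greater in cortex (14 adjusted over the list alone, camera adjusted p = 0.0071), and of 18 neuron markers 5 were lower (10 adjusted over the list alone, camera adjusted p = 0.107). edgeR called 151 genes greater and 243 lower of 13842, and limma voom 196 greater and 135 lower. The count was 185 without cortex zone 2 replicate 4 and 23 with all IP groups in one fit, where the calls of Mag, Sox10 and Snap25 were lost; limma voom also ended the call of Snap25. In zone 4 edgeR called 5 genes greater and 24 lower of 14176, 0 in all without cortex zone 4 replicate 3 and 112 without white matter uninjured IP replicate 3; Gfap and Mbp did not pass, at 0.93 ± 0.41 and −0.01 ± 0.40. In zone 3 edgeR called 0 genes, 1966 had an unadjusted p under 0.05, DESeq2 called 418 and limma voom 0, with Gfap at 1.14 ± 0.65 (−0.12 in DESeq2). Without white matter zone 3 replicate 1 Gfap stood at 1.82 there, and without replicate 2 edgeR called 72 genes. In zone 5 edgeR called 0, 1629 had an unadjusted p under 0.05, DESeq2 called 238 and limma voom 0, with Gfap at 0.16 ± 0.59 (−0.19 in DESeq2).

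Zone 1 was also compared with zone 5 of the same region. In cortex, Gfap was higher in zone 1 by 3.58 ± 0.27, Vim by 5.96 ± 0.42, C4b by 6.59 ± 0.50, C1qb by 4.96 ± 0.24, Abca1 by 3.42 ± 0.21 and the glutamate transporter gene Slc1a3 by 0.83 ± 0.18. Hmgcs1 was lower, at −1.89 ± 0.29. All 16 of 16 microglia and macrophage markers were higher (16 adjusted over the list alone, median 3.58, camera adjusted p = 0.000773), as were 13 of 15 oligodendrocyte markers (14 adjusted over the list alone, camera adjusted p = 0.00392). Among 20 astrocyte markers 6 were higher (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00514), and of 18 cholesterol synthesis genes 3 were lower (6 adjusted over the list alone, camera adjusted p = 0.0051). edgeR called 831 genes higher and 171 lower of 13378, and 664 in all without zone 5 replicate 1. In white matter, Ctsd was higher in zone 1 by 4.21 ± 1.04 (3.18 without zone 1 replicate 1), a call lost without zone 1 replicate 1 or zone 5 replicate 3, with DESeq2's size factors and with the CPM filter; 1 of 16 microglia and macrophage markers was higher (11 adjusted over the list alone, camera adjusted p = 0.107). edgeR called 12 genes higher and 12 lower of 9873. The count was 0 without zone 1 replicate 1 and 216 without zone 1 replicate 3, and 0 without the shallow libraries.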

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

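The tests of microglial RNA in IP against input, of receptor counts against depth and of oligodendrocyte markers in white matter zone 4 were chosen after their results were seen, as were the count without the shallow libraries and the scores without single libraries. No plan was recorded for the scores of the other white matter zones. The remaining tests of this part were chosen before. Group sizes are 5 libraries except where stated, and permutation tests are 2-sided and exact.

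All 16 microglia and macrophage markers tested in cortex zone 1 rose in IP libraries described as enriched for astrocytes, with C1qb at 576 ± 165.5 CPM outside ribosomal RNA against 26.1 ± 11.7 in uninjured IP (SD). Shallow libraries are argued against as the source, because 16 markers still rose without them. RNA of microglia and macrophages carried into the IP is a candidate explanation: relative to astrocyte markers, these markers were lower in IP than in input of cortex stroke zones 1 to 3 by a mean log2 difference of −0.76, with every IP library (−2.50 ± 0.37, SD, n = 3) below every input library (−1.74 ± 0.20), and an exact permutation p of 0.1 that is the smallest 3 against 3 libraries allow; in uninjured cortex the difference was −0.80 (−2.49 ± 0.32 against −1.69 ± 0.30, exact p = 0.00794). Both lists share in this difference, since median log2 fold changes of IP over input in stroke zones 1 to 3 were 0.51 for astrocyte and −0.35 for microglia markers (1 of 16 higher and 2 lower past the threshold), and C1qb goes against it at 74.15 CPM in IP and 47.75 in input there and 26.1 and 20.99 in uninjured cortex. Input of stroke zones 1 to 3 also held more receptor counts than IP (1638 ± 819 against 81.1 ± 23.9 CPM outside ribosomal RNA, SD). Such input could make little-expressed genes lower in IP whatever their cell of origin. The score was about as low in uninjured cortex, and zone 1 alone had no input. It therefore cannot decide whether carried-over RNA gave the rise in zone 1. Of the list's 18 members 11 were already tested in uninjured cortex and 3 stand in another list as well, and transcription of these genes in astrocytes after stroke stays open, since no measurement here separates it from carried-over RNA.

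In uninjured cortex, genes that the brain scarcely transcribes were lower in IP than in input. Fewer counts in the IP are argued against: the lowest input library had 8.91 times the olfactory and vomeronasal receptor counts of the highest IP library (2049 against 230), while counts outside ribosomal RNA differed between any input and IP library by at most 2.07 times in favour of input (2069933 against 1000508). With libraries thinned to one number of counts input had 16.6 times the detected receptor genes of IP, which adds little because mean counts were 1942900 in IP and 1574700 in input, and 1412000 in IP without IP replicate 4. Genomic DNA or unspliced RNA in the input may contribute, since receptor CPM outside ribosomal RNA were 31.9 times as high in input (2846 against 89.3; exact permutation p = 0.00794), and 19.0 times without input replicate 1 (1695 against 89.3; p = 0.00794). These measures do not separate DNA from unspliced RNA, nuclear RNA kept in the lysate and absent from ribosomes would give the same value, and no biological explanation was tested.

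Snap25 was called higher in IP of white matter zone 4, as 1 of 17 neuron markers (8 adjusted over the list alone, camera adjusted p = 0.437), a call lost without zone 4 replicate 4 or any of the uninjured IP libraries and with all IP groups in one fit. Grey matter within the captured tissue is a candidate explanation: genes higher in cortex than in white matter input, outside the neuron list, rose relative to all tested genes by 1.47 on the log2 scale (2.40 ± 1.12 in zone 4, 0.93 ± 0.40 in uninjured IP, SD; exact permutation p = 0.00794), and by 1.52, 1.29, 1.08 and 1.37 in zones 1, 2, 3 and 5 (p = 0.00794, 0.0159, 0.0635 and 0.0318); zone 3 gave 0.71 without replicate 1 and 1.46 without replicate 3 (p = 0.135 and 0.00794), and zone 5 gave 0.84 without replicate 3 (p = 0.0556) and p from 0.0556 to 0.0714 without uninjured IP replicate 1, 2, 4 or 5. A lower share of oligodendrocyte RNA cannot be told apart from no such change, because oligodendrocyte markers differed by −0.64 with a spread of 0.97 (SD) between the zone 4 libraries (exact permutation p = 0.103; −0.21 without zone 4 replicate 3, and −0.81 with p = 0.0318 without replicate 1). In zones 1, 2, 3 and 5 they differed by −1.07, −0.98, 0.53 and −0.53 (exact permutation p = 0.222, 0.00794, 0.262 and 0.0556), where zone 1 gave −1.78 without replicate 1 (p = 0.00794) and −0.605 without replicate 3, zone 3 gave 0.25 without replicate 1 and 0.88 without replicate 2 (p = 0.0318), and zone 5 gave −0.67 without replicate 1 (p = 0.0238). A response of neurons or axons to stroke stays open and untested, as a general rise of neuronal transcripts would give the same values.

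Of 182 tests (Dixon's Q) for a single library far from the rest of its group, 18 stood apart. Chance gives about 1 in 20 only for independent, normally spread values. Many of these tests used the same libraries, and library totals and receptor CPM were not on a log scale. The share that stood apart therefore does not measure an excess over chance. Receptor CPM outside ribosomal RNA were 1721 in white matter zone 1 replicate 5 (others 20.94 to 246.9), 236 in cortex zone 1 replicate 1 (71.3 to 111.8) and 7451 in cortex uninjured input replicate 1 (1280 to 2124). Mitochondrial ribosomal RNA took 57.26% of the counts of white matter zone 4 replicate 4 (73.35% to 79.55% in the others). Total counts were 15599775 in cortex zone 2 replicate 5 (21908965 to 24396128).

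The remaining library values are log2(CPM + 1). Cortex uninjured input replicate 1 stood at 3.227 for Aqp4 (others 5.708 to 5.839), 9.495 for Slc1a2 (11.13 to 11.45) and 11.49 for Snap25 (13.21 to 13.83). Gfap was 8.639 in cortex zone 2 replicate 5 (9.977 to 10.19) and Mbp 8.86 in cortex zone 4 replicate 2 (9.457 to 9.667). Vim was 2.056 in white matter zone 5 replicate 3 (6.084 to 7.675), 4.567 in white matter uninjured input replicate 3 (5.745 to 6.208) and 4.195 in white matter uninjured IP replicate 3 (5.793 to 6.003). Aqp4 was 5.333 in white matter zone 1 replicate 5 (8.011 to 8.442) and 5.979 in white matter zone 2 replicate 5 (8.437 to 9.357). Slc1a2 was 14.89 in white matter zone 5 replicate 3 (11.77 to 12.43). Cx3cr1 was 2.728 in white matter zone 3 replicate 1 (6.456 to 7.696) and 4.914 in white matter zone 5 replicate 1 (6.203 to 6.461).

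The interaction test in edgeR cannot tell region from stroke model. It called 274 genes as differing between the regions in their response in zone 1, 394 in zone 2 and 29 in zone 4. These counts depended on single libraries: they ran from 94 (without cortex uninjured IP replicate 5) to 868 (without white matter zone 1 replicate 1), from 185 (without cortex zone 2 replicate 4) to 633 (without white matter zone 2 replicate 4), and from 0 (without cortex zone 4 replicate 3) to 112 (without white matter uninjured IP replicate 3). With all IP groups in one fit they were 483, 23 and 6.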

How the results depend on the processing

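The fits without the shallow libraries were chosen after the data were seen; the other alternatives were chosen before the data were examined. Of 126 named gene calls 0 changed sign under any of them and 16 moved by over 1.5-fold with a library left out, while 14 of 39 named values without a call changed sign in at least 1 fit, and the causes of the shifts below were not tested. Genes whose call did not hold with a library left out were mostly kept out of the text. The counts for named calls therefore do not measure the stability of all calls. Simulated changes were placed only in genes of higher mean counts. Of 8-fold changes 27.3% were recovered in white matter zone 1 and 100% in cortex zone 1. Changes of that size can therefore go uncalled in white matter zone 1. Of 78 list results past the threshold in camera with an estimated correlation, 78 kept their side with a preset correlation, 77 with RLE size factors and 77 with fry. RLE factors ended the call of antigen presentation in white matter zone 1 (adjusted p = 0.0532) and fry that of oligodendrocyte markers in cortex zone 3 (0.0571). The 165 named gene results were fitted under each setting except for the CPM filter (164), all IP groups in one fit (115) and the fits without the shallow libraries (74), and calls changed as follows: DESeq2 added 4 calls, limma voom added 5 and ended 4, no low-count filter added 10 and ended 1, the CPM filter ended 1, RLE factors ended 2, all IP groups in one fit added 4 and ended 18, and the fits without the shallow libraries added 3 and ended 1. Fits with 1 library left out added 16 calls and ended 41.

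DESeq2 called 368 genes in white matter IP against input, 137 in white matter stroke IP against input, 134 and 2 in the enrichment differences of white matter and cortex, 575, 599, 106, 311 and 23 in white matter zones 1 to 5, 12 and 16 in cortex zones 3 and 4, 908, 898, 418, 392 and 238 in the region differences of zones 1 to 5, and 67 and 1526 in zone 1 against zone 5 of white matter and cortex. With no low-count filter edgeR called 210, 123 and 7349 genes in IP against input of white matter, white matter stroke and cortex, 88 and 3 in the enrichment differences, 540, 525, 428, 317 and 384 in white matter zones 1 to 5, 747, 32, 37 and 8 in cortex zones 2 to 5, 714, 725 and 2 in the region differences of zones 1, 2 and 5, and 433 in white matter zone 1 against zone 5. Limma voom with sample quality weights called 821, 404, 13 and 61 genes in white matter zones 1 to 4, 624 and 3 in the region differences of zones 1 and 4, and 80 in white matter zone 1 against zone 5. With all IP groups in one fit edgeR called 14, 0, 30, 0 and 1 genes in white matter zones 1 to 5, 2179 and 5 in cortex zones 1 and 3, 483, 23, 425, 6 and 143 in the region differences, and 2 and 2629 in zone 1 against zone 5 of white matter and cortex. Without the shallow libraries it called 410 and 5 in white matter zones 1 and 3, 1003, 24 and 16 in the region differences of zones 1, 3 and 5, and 0 in white matter zone 1 against zone 5. RLE size factors gave 1 gene in the region difference of zone 3 and 0 in white matter zone 1 against zone 5, where the CPM filter gave 1. RLE factors also moved the median of all genes by 0.151 and 0.121 in white matter zones 3 and 5, and by −0.277 and −0.219 in the region differences of zones 3 and 5.

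The balance of higher and lower calls turned in some fits. Limma voom called 23 higher and 38 lower in white matter zone 4, 2089 and 1661 in cortex against white matter IP, and 332 and 292, 196 and 135, and 2 and 1 in the region differences of zones 1, 2 and 4. With no low-count filter cortex against white matter IP had 2163 higher and 1630 lower. Without single libraries it turned in cortex stroke IP against input (IP replicates 1 to 3: 856 and 682, 891 and 772, 870 and 622), in white matter zone 4 (0 or 1 higher and 2 lower without zone 4 replicate 2 or 4 or uninjured IP 1, 2, 4 or 5) and in the region difference of zone 1 (cortex zone 1 replicates 1 to 5: 88 and 63, 81 and 77, 63 and 51, 62 and 49, 95 and 75; cortex uninjured IP 1, 3 and 4: 66 and 64, 63 and 57, 57 and 50).

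The rule used for pairing by replicate number was not met, since no comparison had every same-numbered pair correlated above 0.1. Yet 3 of 5, 3 of 3, 3 of 5 and 3 of 3 pairs of IP and input correlated best with their own number in white matter, white matter stroke, cortex and cortex stroke. Pairing of IP with input by number therefore stays possible, and the main tests and permutation p-values did not use it. With the replicate number as a block, 5 named gene calls were added and counts were 1 in the white matter enrichment difference, 90, 20 and 2 in white matter zones 1, 4 and 5, 8 in cortex zone 3, 135, 231, 2 and 1 in the region differences of zones 1 to 4, and 2 in white matter zone 1 against zone 5; the other counts stayed within 1.5 times. The block turned the balance of cortex IP against input to 1439 higher and 1316 lower, of cortex against white matter IP to 1598 and 1287, and of the region difference of zone 1 to 77 and 58.

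Leaving out 1 library gave 32 to 121 genes in white matter IP against input (input replicates 1, 3 and 5 gave 43, 39 and 32, IP replicates 1 and 5 121 and 41), 0 to 0 in white matter stroke, 2277 to 3666 in cortex, 1492 to 5329 in cortex stroke (input replicate 2 5329, IP replicates 1 to 3 1538, 1663 and 1492), 0 to 1 in the white matter enrichment difference (stroke IP replicate 2) and 0 to 0 in the cortex one. In white matter zone 1 it gave 5 to 270 (zone 1 replicates 1, 3 and 4: 270, 129 and 22; uninjured IP 1 to 5: 11, 5, 19, 6 and 9), in zone 2 47 to 139 (zone 2 replicates 2 and 3: 49 and 53; uninjured IP 1, 2 and 4: 54, 47 and 65), in zone 3 0 to 5 (zone 3 replicate 1), in zone 4 2 to 13 (zone 4 replicates 2 and 4: 3 and 2; uninjured IP 1, 2, 4 and 5: 2, 2, 2 and 3) and in zone 5 0 to 37 (zone 5 replicates 1, 2, 4 and 5: 37, 4, 14 and 29). Cortex zones 1 and 2 gave 477 to 881 and 329 to 512, zone 3 2 to 17 (zone 3 replicates 3 to 5: 5, 6 and 5; uninjured IP 4: 17; uninjured IP 2: 2), zone 4 0 to 12 (zone 4 replicate 4: 2; uninjured IP 3 and 4: 2 and 12), zone 5 0 to 3 (uninjured IP 4), and cortex against white matter IP 2459 to 3710.

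Region differences in zone 1 ran from 94 to 868 (white matter zone 1 replicates 1 and 5: 868 and 438; white matter uninjured IP 1: 158; cortex zone 1 replicates 1 to 5: 151, 158, 114, 111 and 170; cortex uninjured IP 1 to 5: 130, 114, 120, 107 and 94), in zone 2 from 185 to 633 (white matter zone 2 replicate 4: 633; white matter uninjured IP 3: 632; cortex zone 2 replicates 1 to 5: 245, 196, 229, 185 and 240; cortex uninjured IP 1, 3, 4 and 5: 248, 229, 243 and 212), in zone 3 from 0 to 72 (white matter zone 3 replicates 1, 2, 3 and 5: 24, 72, 44 and 9), in zone 4 from 0 to 112 (white matter zone 4 replicates 1 to 5: 48, 52, 50, 73 and 79; white matter uninjured IP 3 and 5: 112 and 57; cortex zone 4 replicates 1 to 5: 3, 3, 0, 3 and 8; cortex uninjured IP 2 to 5: 8, 3, 3 and 8) and in zone 5 from 0 to 37 (white matter zone 5 replicates 1, 3, 4 and 5: 37, 16, 3 and 16; white matter uninjured IP 3 and 4: 1 and 4). Zone 1 against zone 5 ran from 0 to 216 in white matter (zone 1 replicates 1 to 5: 0, 141, 216, 153 and 187; zone 5 replicates 1 to 5: 206, 200, 1, 207 and 208) and from 664 to 1434 in cortex (zone 5 replicate 1: 664).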

Other observations

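The comparison of directions between regions was chosen after the results were seen; the regroupings of libraries were planned.

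Further gene groups moved in cortex zone 2. Of 7 antigen presentation genes 4 rose (5 adjusted over the list alone, camera adjusted p = 0.00449), of 11 proteoglycan genes 3 (6 adjusted over the list alone, camera adjusted p = 0.0138), of 6 matrix proteases and inhibitors 4 (4 adjusted over the list alone, camera adjusted p = 0.013) and of 5 cell cycle genes 3 (5 adjusted over the list alone, camera adjusted p = 0.00985). Of 10 oligodendrocyte precursor markers 2 rose (2 adjusted over the list alone), and that list did not pass camera (adjusted p = 0.0505).

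The regions were also set beside each other zone by zone, using separate libraries. Of the 685 genes called in cortex zone 1, 586 were tested in white matter zone 1, and 390 of these (66.6%) had the same sign there, where 51.3% of all tested genes were positive; 18 were called in both. In zone 2, 234 of 396 (59.1%) had the same sign, with 50.6% of all tested genes positive, and 21 were called in both.

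Other splits of the same libraries into groups of the same sizes were fitted with edgeR, 22 for each comparison with the real one included, and 10 where 3 libraries stood against 3. Such splits mix the groups, so any real difference adds to their spread within groups and can lower their counts. Where only the real one of 22 splits gave as many genes, chance is argued against at 0.05, with no adjustment over the 24 comparisons. This held for white matter IP against input (73 genes, highest other split 0), cortex IP against input (2902, 0), cortex against white matter IP (3104, 0), cortex zone 1 (685, 0), cortex zone 2 (443, 4), white matter zones 1, 2 and 4 (47, 101 and 9, each 0), and cortex zone 1 against zone 5 (1002, 0). The region differences in zones 1, 2 and 4 gave 274, 394 and 29 genes, with 5, 178 and 1 in the highest other split. Their splits mixed zone with uninjured libraries within each region, which removes the stroke response of both regions. They therefore cannot tell whether chance gave the differences between regions. Chance cannot be excluded for cortex zone 3, where 2 of 22 splits gave as many as the real 3 genes and the highest other gave 8. It cannot be excluded for white matter zone 1 against zone 5 either, where 10 of 22 splits gave 24 genes or more; another split gave 226, which may point to a structure of these libraries apart from the zones that was not tested. The real count was 0, so that 22 of 22 splits gave as many, for the enrichment difference in both regions (highest other 0), white matter zones 3 and 5 (0 and 1), cortex zones 4 and 5 (1 and 48), and the region differences in zones 3 and 5 (2 and 1). The split with 48 genes in cortex zone 5 may likewise point to a structure of those libraries, also untested. For stroke zones 1 to 3, 10 splits are too few for a share under 0.05: IP against input gave 3479 genes in cortex (highest other 0, 1 of 10 splits as high) and 0 in white matter (highest other 0, 10 of 10).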
